A study of Mus musculus with 12 samples.

How the data were processed

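The series measured RNA from sorted mouse thymocytes on 12 Affymetrix MOE430B arrays, with 1 colour and 1 array per sample. Mice on the B10 background carried a transgenic T cell receptor alone, called TCR, or the receptor together with a transgene for its antigen, called TCR:HEL. From each kind of mouse the labels give CD4 single-positive thymocytes and double-positive thymocytes, so that there were 4 groups of 3 biological replicates. Groups were taken from the sample titles. The series design text names one of the mice only as B10, so the titles were used for what each mouse carried. Mice were 6 to 8 weeks old. Per the labels, total RNA was extracted from sorted cells with Trizol and RNeasy columns, and RNA of 100000 to 1000000 cells was labelled with biotin by a small-sample protocol with repeated amplification.

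The deposited table holds MAS5 signals, which are intensity values on a linear scale, and the authors' processing notes name MAS5 without a version or settings. The 2% trimmed mean was 150 on every array, so all arrays had been scaled to a common level and the values were used as scaled. No detection calls were used here. The deposited record files of the arrays hold other information than expression, namely chip type, chip lot and hybridization day, and were used to look for batches. All 12 arrays were of 1 chip lot and were hybridized on 8 days. The arrays' number, 3 per group, limits the precision of every comparison.

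The table has 22575 probe sets. After removal of 64 control probe sets, probe sets above their array's median on at least 3 of the 12 arrays were kept, which left 13703. The platform annotation gave 1 gene symbol to 9319 of these, several to 149 and none to 4235. Symbols were updated through a table of RefSeq genes of GRCm38.p6, and no positions are given because the build behind the array design was not stated. Of the probe sets kept, 1029 had clone-type names, and these were counted but not named. Signals were transformed as log2(signal + 16). All fold changes below are on this scale, which understates the change of genes with low signal.

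Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 12 arrays, followed by empirical Bayes moderation with a trend, which gave 8 residual and 7.01 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with calls at an adjusted p under 0.05. The 5 contrasts were TCR:HEL minus TCR in single-positive cells, the same in double-positive cells, single-positive minus double-positive in TCR, the same in TCR:HEL, and the interaction, that is, the difference between the TCR:HEL effects of the 2 stages.

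Gene groups were tested as 29 lists fixed before the data were examined, together with the model, the comparisons and the rule for naming genes. They covered T cell receptor signalling, apoptosis, thymocyte stages, T cell lineages, the cell cycle, interferon response, metabolism, stress, and markers of other cell types. Limma's camera was run with a preset correlation of 0.01 on 1 probe set per gene, the probe set with the highest mean, and lists needed at least 5 measured genes. This left 22 lists, and p-values were adjusted over these within each contrast. The arrays held only part of every list, for example 14 of 62 pro-apoptotic genes, so a list's result covers its measured genes alone. A list's shift is the median log2 fold change of its genes minus that of the other measured genes. Camera with an estimated correlation and fry were run beside it. Fry tests a list against no change, not against the other genes.

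Genes were named by rule. Among called probe sets whose groups did not overlap and that had 1 symbol, the 10 with the highest and the 10 with the lowest fold change were taken, and all of them where fewer passed. Up to 4 members with the smallest p of each list and 36 genes used to check sorting and signalling were added. Of these 36, 7 were measured, namely Cd8a, Cd69, Nr4a2, Nr4a3, Egr3, Bcl2 and Ikzf2, and Foxp3, Cd4, Nr4a1 and Bcl2l11 were among the other 29. Where nothing was called, the 10 probe sets with the smallest p were taken as values. Where a gene had several probe sets, the one with the highest mean was used.

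The record files place the 12 arrays in 3 hybridization periods parted by gaps of over 35 days. No gap had been fixed beforehand. It was first set to 30 days, which gives 4 periods, and was changed to 35 days after the hybridization days had been seen. Both versions were run. Period 1 held TCR and TCR:HEL single-positive replicate 1. Period 3 held TCR single-positive replicate 3, TCR:HEL single-positive replicates 2 and 3 and TCR:HEL double-positive replicate 3. Period 2 held the other arrays. Replicate numbers were checked as pairs by correlating each array's deviations from its group mean across probe sets. Between the single-positive groups arrays of the same number correlated at r = 0.16, 0.20 and 0.19, and between the stages in TCR:HEL mice at 0.09, 0.11 and 0.20, the highest value for each, so fits with the number as a block are given beside these comparisons. Between the double-positive groups and between the stages in TCR mice not all 3 numbers did so, and there the number is treated as a label.

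Alternatives to the pseudocount, the filter, the scaling, the moderation, the array weights, the probe sets that stand for a gene in a list, the arrays in the fit, a block for replicate number, and each array left out were run. A block for the period had been fixed too, but its 35-day gap was not. A further 4 alternatives were chosen after seeing the data, namely hybridization day as a random block, the 30-day gap, the Gapdh 5' to 3' signal ratio as a covariate, and a fit without the 2 arrays of period 1. The method was tested on simulated data of the same size with 200 changed probe sets, in 5 simulations. In the comparison of single-positive cells it recovered 65.2% of probe sets changed by 2 on the log2 scale and 9.0% of those changed by 1, with 3.4 false calls on average and 0 calls of the wrong sign. For the interaction it recovered 20.6% and 0.4%. The simulated noise was normal and independent between probe sets and arrays, without hybridization periods, so these rates need not hold for the real arrays.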

Results

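RNA levels were measured in CD4 single-positive and double-positive thymocytes of mice with a transgenic T cell receptor alone (TCR) and of mice that also carried the receptor's antigen (TCR:HEL). Per the labels, TCR single-positive cells stand for positive selection and TCR:HEL single-positive cells for negative selection, and double-positive cells are the stage before. Each of the 4 groups had 3 arrays. Median signals per array lay between 63.0 and 81.3. Pearson correlations of log2 signals between arrays of 1 group ran from 0.816 to 0.892. The first principal component, with 25.8% of the variance, placed all 6 single-positive arrays (-55.2 to -18.7) apart from all 6 double-positive arrays (17.6 to 45.3). Stage and hybridization period largely coincided. Period 2 held TCR replicate 2 as its only single-positive array, and all double-positive arrays but TCR:HEL replicate 3. Those exceptions lay at -18.7 and 17.6, on the side of their stage. TCR single-positive replicate 1 stood apart on the next component (64.9) and TCR:HEL single-positive replicate 1 on component 4 (58.0). These arrays, the only ones of hybridization period 1, and TCR double-positive replicate 1 had the lowest Gapdh 5' to 3' signal ratios. They were 0.0379, 0.0856 and 0.107, against 0.195 to 0.453 on the others, a ratio that falls when RNA is degraded. The actin ratio was lowest on TCR single-positive (0.120), TCR:HEL double-positive (0.169) and TCR double-positive replicate 1 (0.184). On TCR:HEL single-positive replicate 1 it was 0.376, so the actin ratio did not set that array apart.

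The comparison of TCR:HEL with TCR single-positive cells asked which genes differ between cells under negative and positive selection. Dusp4, a phosphatase that dampens MAP kinase signalling, rose from a signal of 204 ± 32.8 in TCR to 1536 ± 254 in TCR:HEL cells (SD, n = 3 arrays each), a log2 fold change of 2.82 ± 0.29 (SE). Ikzf2, which encodes the transcription factor Helios, rose from 1168 ± 244 to 6197 ± 858, by 2.40 ± 0.26. Niban1 rose by 2.51 ± 0.29, and the channel gene Trpm1 rose by 3.18 ± 0.41 from a signal of 155 to 1327. Adjusted p was 0.000565 for Dusp4 and Ikzf2, 0.000941 for Niban1 and 0.00281 for Trpm1. These 4 genes passed in every alternative fit that held them. The filter on 6 arrays removed Trpm1.

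Further genes higher in TCR:HEL single-positive cells were the helicase gene Pif1 (2.40), Osbp2 (2.34), the centromere motor gene Cenpe (2.23), Arhgap20 (2.16), Sgo1 (1.88), which protects cohesion between sister chromatids, and Prr5l (1.73). Lower were Tmie (-3.13 ± 0.45), the chromatin remodeller gene Chd7 (-2.99 ± 0.56), Rflnb (-2.53 ± 0.42), Mn1 (-1.77), Als2cl (-1.53) and the carboxypeptidase gene Cpm (-1.45). Rflnb went from 616 ± 30.9 to 96.2 ± 29.8 and Tmie from 951 ± 341 to 101 ± 55.1 (SD, n = 3). A second probe set of Rflnb (0.57) and one of Trpm1 (0.04) did not follow. These 12 genes each missed the threshold under at least 1 alternative, with adjusted p of up to 0.341 for Cenpe, and each of the 6 arrays ended the call of at least 1 of them when left out. Tmie lost its call only without the arrays of period 1 (-2.56, adjusted p = 0.0768).

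Of the genes chosen to check signalling, Ikzf2 passed. Nr4a3, a nuclear receptor gene induced by T cell receptor signals, had signals of 1097 ± 213 in TCR and 4910 ± 1802 in TCR:HEL single-positive cells, with a log2 fold change of 2.10 ± 0.44 and an adjusted p of 0.0708. The activation marker Cd69 had 1.19 ± 0.35 (adjusted p = 0.306) and Egr3 0.26 ± 0.40. Nr4a2 had 1.16 ± 0.44 (adjusted p = 0.560) on the probe set used, while another of its probe sets, at 3.24, was called. The coreceptor gene Cd8a had 0.73 ± 0.27 (adjusted p = 0.536), with signals of 651 ± 117 and 1118 ± 391, and the survival gene Bcl2 0.15 ± 0.29.

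In all, limma called 30 of 13703 probe sets between the single-positive groups, 20 higher and 10 lower in TCR:HEL, among them 15 named genes higher and 6 lower, and 985 had an unadjusted p under 0.05 where 685 would be expected by chance. Values of the groups did not overlap in 1457 probe sets (10.6%), where chance gives 10%. The count fell to 18 without TCR replicate 3 and to 15, 17 and 13 without TCR:HEL replicates 1, 2 and 3, and was 16 without the arrays of period 1, of which 13 were among the 30. With the replicate number as a block it was 47, which held all 30, and with the hybridization period as a block 33, of which 28 were shared. In the same-day pairs of arrays, Ikzf2 differed by 2.97 and 2.25 and Dusp4 by 2.70 and 2.81.

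**Figure D1:**
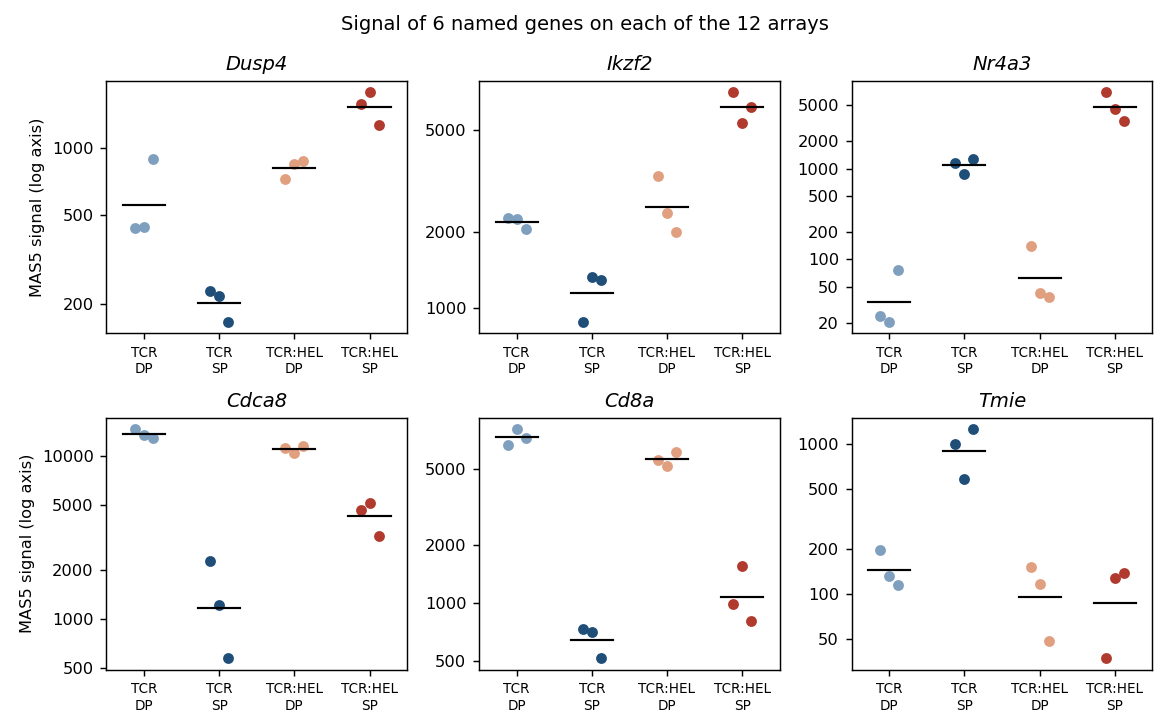
MAS5 signal (log axis) of Dusp4, Ikzf2, Nr4a3, Cdca8, Cd8a and Tmie on each of the 12 arrays; points are arrays, 3 per group, and lines are geometric means of the 3. Dusp4 and Ikzf2 are highest in TCR:HEL single-positive cells (mean signals 1536 and 6197), and Tmie is highest in TCR single-positive cells (951).

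Genes of the cell cycle shifted up in TCR:HEL single-positive cells relative to the other measured genes. Of 75 measured members, 62 had a positive fold change, Cenpe and Sgo1 rose, 73 did not pass, and 21 rose when adjusted over the list alone. Depdc1b (1.84, adjusted p = 0.0576) and the chromosomal passenger gene Cdca8 (1.85, adjusted p = 0.0602) had the next smallest p-values. Cdca8 signals were 1357 ± 864 in TCR and 4356 ± 1009 in TCR:HEL single-positive cells, against 13682 in TCR double-positive cells (SD, n = 3), and 2 further probe sets of Cdca8, at 2.92 and 2.48, were called. The list's median shift was 0.64 log2 (camera adjusted p = 2.1e-16, and adjusted p = 0.00881 with an estimated correlation). With the period as a block it was 0.56, within period 1 it was 0.43 and within period 3 it was 0.71, and with no filter on low values it was 0.40.

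Transcription factors induced by T cell receptor signals shifted up by 0.27 (15 genes, adjusted p = 0.00124, and adjusted p = 0.0417 with an estimated correlation). Of these Ikzf2 rose, 14 did not pass, and 3 rose when adjusted over the list alone. Nr4a2 was among those that did not pass, although another of its probe sets was called higher. The AP-1 gene Fosl2 had 1.91 ± 0.50 and Tox2 1.15 ± 0.42. The shift was 0.23 with the period as a block, 0.61 within period 1 and 0.28 within period 3, and it was 0.44 without TCR replicate 1 and 0.42 without TCR:HEL replicate 3. Genes of mature single-positive cells and thymic egress shifted down by 0.41 as a list (shift -0.41, 25 genes, adjusted p = 9.8e-06, and adjusted p = 0.0247 with an estimated correlation). Als2cl fell, 24 did not pass, and adjusted over the list alone 7 fell and 1 rose. Among them Gimap7, of a family of lymphocyte GTPases, had -1.62 ± 0.32 (adjusted p = 0.0602) and Slfn5 -1.04 ± 0.29. The shift was -0.38 with the period as a block, -0.39 within period 1 and -0.67 within period 3.

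Regulatory T cell genes had a median shift of 0.16 and a mean shift of 0.53 (15 genes, adjusted p = 0.00222), and adjusted p = 0.119 with an estimated correlation. Ikzf2, Niban1 and Arhgap20 rose, 12 did not pass, and 4 rose when adjusted over the list alone. Foxp3, the defining factor of these cells, was not measured. The median shift was 0.07 with the period as a block, -0.07 within period 1 and 0.57 within period 3, and without TCR replicate 3 it was 0.37 with an adjusted p of 0.111. Without TCR replicate 2 the median shift was -0.04, although camera still called the list higher, and without TCR:HEL replicates 1 and 2 it was 0.25 and 0.08.

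Among the other lists, no call was made between the single-positive groups in the fit of 4 group means to all 12 arrays. The number of lists called was higher in some fits with 1 array left out. Oxidative phosphorylation genes had a shift of 0.29 (12 of 12 members positive, adjusted p = 0.0543) and CD4 lineage genes -0.33 (adjusted p = 0.122). Feedback regulators of receptor and MAP kinase signalling had 0.01, although Dusp4 is a member, and costimulatory and inhibitory receptors 0.02. Shifts were -0.08 for the NF-kB pathway, 0.00 for pro-apoptotic and 0.02 for anti-apoptotic genes. These lists had 14 of 43, 11 of 62 and 13 of 37 genes measured, and the pro-apoptotic mean shift was 0.24. Most of the listed apoptosis genes were thus not seen. Further shifts were 0.12 for double-positive stage genes, -0.07 for interferon-stimulated genes, -0.12 for proximal receptor signalling and 0.04 for calcium and NFAT signalling. They were -0.09 for glycolysis and hypoxia, 0.05 for cholesterol biosynthesis, 0.01 for heat shock and the unfolded protein response and -0.29 for cytokines and chemokines. Marker lists gave 0.28 for B cells, -0.02 for dendritic cells and macrophages and -0.11 for NK, NKT and gamma-delta cells. Median and test differed in sign for calcium and NFAT signalling and for NK, NKT and gamma-delta cells, and none of these shifts passed. Fewer than 5 genes were measured for ribosomal proteins (3), sex-linked genes (2), and markers of erythroid cells and platelets (2), thymic epithelium and stroma (4), CD8 single-positive cells (4), double-negative thymocytes (4) and granulocytes and mast cells (0), so these lists were not tested. Of the marker lists, that of CD8 single-positive cells had the highest median log2 fold change, 0.67. Of its genes 0 passed and 2 were higher when adjusted over the list alone, with Itgae at 1.15 ± 0.31, Cd8a at 0.73, Il18rap at 0.61 ± 0.57 and Runx3 at -0.44 ± 0.35.

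The comparison of TCR:HEL with TCR double-positive cells asked whether the antigen's effect was present before the single-positive stage. The smallest p belonged to the receptor gene segment Trav6-3, with signals of 333 ± 22.7 in TCR and 89.1 ± 39.2 in TCR:HEL cells (SD, n = 3) and a log2 fold change of -1.80 ± 0.30 (adjusted p = 0.320). Acoxl had -1.73 ± 0.39, Klhl28 -1.31 ± 0.30, and the class II peptide-loading gene H2-DMb2 1.81 ± 0.48. Ikzf2 had 0.19 ± 0.26, Dusp4 0.53 ± 0.29 and Nr4a3 0.64 ± 0.44. Limma called 0 probe sets, in this fit and under every alternative run, and 339 had an unadjusted p under 0.05, fewer than the 685 expected by chance. Values did not overlap in 1051 probe sets (7.67%, against 10% by chance).

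Among gene groups in double-positive cells, the 7 measured costimulatory and inhibitory receptors had a median shift of -0.40 in TCR:HEL (adjusted p = 0.00123), and adjusted p = 0.0706 with an estimated correlation. All 7 had a negative fold change and 0 passed, with Icos at -0.67 ± 0.27, Cd44 at -0.73 ± 0.30 and Cd69 at -0.65 ± 0.35. The 5 B cell markers had a shift of 0.50 (adjusted p = 0.0186), and adjusted p = 0.284 with an estimated correlation. All 5 were positive and 0 passed, and 1 passed when adjusted over the list alone, the Fc receptor gene Fcmr (1.26 ± 0.35, from 127 to 328), while Pax5 had 0.14 and Ebf1 stayed at signals of 55.6 and 55.1. With the period as a block the shifts were -0.45 and 0.73, and within period 2, which held 3 TCR and 2 TCR:HEL arrays, -0.39 and 0.78. The B cell call was lost without TCR replicate 1 (shift 0.33, adjusted p = 0.285) and without TCR:HEL replicate 1 (shift 0.23, adjusted p = 0.233), and its shift was 0.78 without TCR:HEL replicate 3. That of the receptors was -0.62 without TCR:HEL replicate 1. With the 30-day gap as a block both lists had an adjusted p of 0.0559, and fry, which tests against no change, gave 0.0820 and 0.542.

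Single-positive and double-positive cells of TCR mice were compared to follow the change of stage under positive selection. Nr4a3 rose from a signal of 40.4 ± 31.3 in double-positive to 1097 ± 213 in single-positive cells (SD, n = 3), by 4.42 ± 0.44 (SE). Bach2, a transcriptional repressor gene, rose by 3.21 ± 0.35, the receptor gene Gpr18 by 3.12 ± 0.30, from 805 to 7140, and the integrin gene Itgb3 by 3.09 ± 0.43. The mitotic checkpoint gene Bub1b fell by 4.65 on the log2 scale (SE 0.51), from 7431 ± 922 to 350 ± 235, and the kinetochore gene Spc24 fell by 4.10 (SE 0.37). The coreceptor gene Cd8a fell by 3.47 (SE 0.27), from 7311 ± 680 to 651 ± 117. Adjusted p for these genes lay between 6.1e-06 for Cd8a and 0.000597 for Itgb3, and all 7 passed under every alternative.

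By list, 42 of 75 cell cycle genes fell in TCR single-positive cells and 33 did not pass, with 52 falling when adjusted over the list alone. The phosphatase gene Cdc25c (-3.75), the cyclin gene Ccnf (-3.38) and Clspn (-3.07) were among them, as were Cenpp (-4.33) and Esco2 (-3.77), and the list shifted by -1.44 (adjusted p = 3.0e-37, and adjusted p = 0.000469 with an estimated correlation). Of the mature single-positive and egress genes 6 of 25 rose, 19 did not pass, and 9 rose when adjusted over the list alone. Tgfbr3 (2.55), Gimap7 (2.37) and Slfn5 (2.14) were examples, with a list shift of 0.75 (adjusted p = 8.2e-09). Of 22 double-positive stage genes 4 fell, among them Cd8a and Dgkeos (-2.81), 18 did not pass, 5 fell when adjusted over the list alone, and the shift was -0.73 (adjusted p = 0.000476), or -0.47 with the mean of all probe sets of a gene. Of 26 interferon-stimulated genes 5 rose, among them Nlrc5 (2.01), a regulator of MHC class I genes, and Slfn5, and 21 did not pass, while 9 rose when adjusted over the list alone (shift 0.52, adjusted p = 3.3e-06). Of 7 costimulatory and inhibitory receptors, Icos (2.31 ± 0.27) and Btla (1.44 ± 0.29) rose, 5 did not pass, and 3 rose when adjusted over the list alone (shift 0.68, adjusted p = 0.00403, and 0.35 with no filter on low values, adjusted p = 0.0334). The call of Btla was lost without TCR single-positive replicate 2 (adjusted p = 0.0517) or 3 (adjusted p = 0.0532). The calls of these 5 lists held with an estimated correlation, with adjusted p of 0.0413 for the receptors and the interferon-stimulated genes.

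Calls of 2 more lists in this comparison did not hold. The NF-kB pathway had a shift of 0.43 (14 genes, adjusted p = 0.00403), and adjusted p = 0.137 with an estimated correlation. The inhibitor gene Nfkbid rose (2.12 ± 0.39), 13 did not pass, and 4 rose when adjusted over the list alone. Regulatory T cell genes had a shift of 0.45 (15 genes, adjusted p = 0.0136), and adjusted p = 0.160 with an estimated correlation. Gpr83 (2.56), Ikzf4 (2.39) and Arhgap20 (1.53) rose, the coreceptor gene Nrp1 fell (-1.46), and 11 did not pass. That list's call was lost without TCR single-positive replicate 2 (adjusted p = 0.0596), and Nrp1's without that array (adjusted p = 0.0580) or TCR double-positive replicate 1 (adjusted p = 0.0603). Arhgap20 lost its call without TCR single-positive replicate 1 or 2 or TCR double-positive replicate 1 or 3, with adjusted p of up to 0.113 over all alternatives. Outside the called lists, the sterol regulator gene Insig1 fell (-2.48 ± 0.32), as did the adaptor gene Nck2 (-2.87 ± 0.35) and Tox2 (-2.62 ± 0.42). Dcn, a gene of stromal matrix, rose (1.30 ± 0.31, from 38.1 to 117). Its call was lost without TCR single-positive replicate 1 or 3 (adjusted p = 0.108 and 0.101), without TCR double-positive replicate 1 or 2 (adjusted p = 0.0761 and 0.112) and with the period as a block (adjusted p = 0.259). Of the 4 measured genes of thymic epithelium and stroma, too few for a test, 1 rose, 2 were higher when adjusted over the list alone, and the median log2 fold change was 0.70.

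Limma called 484 probe sets between single-positive and double-positive TCR cells, 153 higher and 331 lower in single-positive cells, with 1913 at an unadjusted p under 0.05 and 17.0% of probe sets without overlap (10% by chance). Of the 50 genes named here and called, 31 kept their call under every alternative that held them. All TCR double-positive arrays lay in period 2 with only 1 single-positive array, TCR replicate 2. The count was 313 with the period as a block, of which 276 were shared, 240 with the 30-day gap, and 293 without TCR single-positive replicate 3. With the period as a block and within period 2 the shifts were -1.55 and -1.53 for the cell cycle, 0.65 and 0.79 for mature single-positive genes, -0.71 and -0.70 for double-positive stage genes, 1.00 and 1.02 for interferon-stimulated genes, 0.95 and 0.83 for the receptors, 0.27 and 0.27 for the NF-kB pathway and 0.43 and 0.55 for regulatory T cell genes. Without TCR single-positive replicate 1 that of interferon-stimulated genes was 0.80.

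The same change of stage was compared in TCR:HEL mice, where single-positive cells meet the antigen. Nr4a3 rose from 74.5 ± 58.2 in double-positive to 4910 ± 1802 in single-positive cells (SD, n = 3), by 5.88 ± 0.44 (SE). Trpm1 rose by 5.05 ± 0.41, Fosl2 by 3.87 ± 0.50, Acoxl by 3.79 ± 0.39, Arhgap20 by 3.59 ± 0.35 and the nuclear lamina gene Lmna by 3.22 ± 0.36. The activation marker Cd69 rose from 566 ± 212 to 3206 ± 564, by 2.52 ± 0.35, and Egr3 by 2.86 ± 0.40. Cd8a fell by 2.36 (SE 0.27), Spc24 by 2.57 on the same scale (-2.57 ± 0.37) and Fbxo5, which encodes an inhibitor of the anaphase-promoting complex, by 2.39 (-2.39 ± 0.24). Adjusted p ran from 1.2e-05 for Nr4a3 to 0.00142 for Spc24 among these genes, and all 11 passed in every alternative that held them. The filter on 6 arrays removed Trpm1 and Fosl2.

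In these TCR:HEL cells, 4 of 15 transcription factors of receptor signalling rose, 11 did not pass, and 6 rose when adjusted over the list alone (shift 0.29, adjusted p = 0.000456). The shift was 0.61 without TCR:HEL single-positive replicate 1, 0.12 without replicate 2 and 0.13 with the filter on 6 arrays, and the call was kept in each. The genes that rose were Nr4a3, Fosl2, Egr3 and Ikzf2 (1.30 ± 0.26). Ikzf2 lost its call without TCR:HEL single-positive replicate 1 (adjusted p = 0.0713) or 3 (adjusted p = 0.0597) and without TCR:HEL double-positive replicate 2 (adjusted p = 0.0860) or 3 (adjusted p = 0.0743). Of 7 costimulatory and inhibitory receptors Icos (2.74), Cd69 and Btla (2.02) rose, 4 did not pass, and 5 rose when adjusted over the list alone (shift 1.15, adjusted p = 4.9e-08). Of 15 regulatory T cell genes Arhgap20, Niban1 (2.89), Ikzf4 (2.77), Gpr83 (2.00) and Ikzf2 rose, 1 fell and 9 did not pass (shift 0.47, adjusted p = 4.5e-06). The gene that fell was Nrp1 (-1.62), which the naming rule did not pick here. Of 26 interferon-stimulated genes 4 rose, among them Nlrc5 (1.93), 22 did not pass, and 9 rose when adjusted over the list alone (shift 0.80, adjusted p = 4.0e-09).

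Cell cycle genes fell here too, 27 of 75, with 48 not passing and 42 falling when adjusted over the list alone. Ccnf (-2.28), E2f7 (-2.31) and Cdc25c (-2.23) were examples (shift -1.05, adjusted p = 1.0e-26). Double-positive stage genes shifted by -0.31 (22 genes, 3 fell, adjusted p = 0.00135), mature single-positive and egress genes by 0.25 (25 genes, 3 rose, adjusted p = 0.000132) and cholesterol biosynthesis genes by -0.40 (10 genes, 1 fell, adjusted p = 0.00137). The gene of the last list was Insig1 (-1.60 ± 0.32), whose call was lost with the period as a block (-1.16, adjusted p = 0.124) and without TCR:HEL single-positive replicate 1, 2 or 3 or TCR:HEL double-positive replicate 1 or 2 (adjusted p = 0.0564, 0.0547, 0.0600, 0.0529 and 0.0990). These calls and those of the preceding lists held with an estimated correlation, the largest adjusted p being 0.0243. The NF-kB pathway had a shift of 0.55 (14 genes, adjusted p = 0.000529), and adjusted p = 0.0505 with an estimated correlation. Nfkbid rose (3.18 ± 0.39) and 13 did not pass.

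Limma called 271 probe sets in this comparison, 120 higher and 151 lower in single-positive cells, with 1705 at an unadjusted p under 0.05 and 18.6% without overlap (10% by chance). The count was 173 and 153 without single-positive replicates 1 and 3, 118 and 175 without double-positive replicates 2 and 3, and 202 with the period as a block, of which 142 were shared. With the replicate number as a block it was 370, of which 270 were shared. With the period as a block and within period 3, which held 2 single-positive arrays and 1 double-positive array, shifts were 0.48 and 0.41 for the transcription factors, 1.38 and 1.40 for the receptors, 0.81 and 0.53 for regulatory T cell genes and 0.88 and 0.83 for interferon-stimulated genes. They were -0.93 and -0.96 for the cell cycle, -0.58 and -0.53 for double-positive stage genes, 0.55 and 0.57 for mature single-positive genes, -0.64 and -0.55 for cholesterol biosynthesis and 0.37 and 0.24 for the NF-kB pathway. With 1 array left out, that of regulatory T cell genes was 0.25 without single-positive replicate 3, that of double-positive stage genes -0.21 without double-positive replicate 2 and that of mature single-positive genes 0.43 without double-positive replicate 3, with each call kept.

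**Figure D2:**
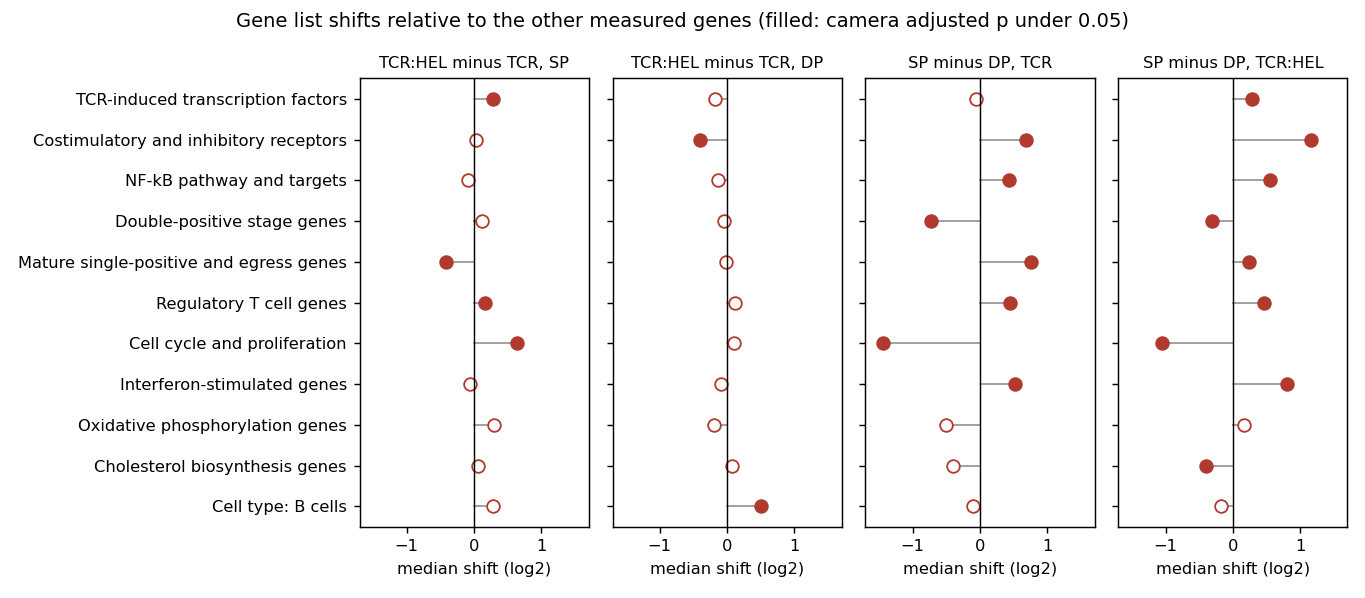
Median shift (log2, x axis) of each gene list that passed in at least 1 comparison, with the 4 comparisons as panels and lists as lines; filled points have a camera adjusted p under 0.05 and open points do not. Cell cycle genes sit at -1.44 and -1.05 in the comparisons of single-positive with double-positive cells and at 0.64 between the single-positive groups.

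The changes of stage in TCR and TCR:HEL mice, which share no arrays, were set side by side. Of the probe sets called in each, 172 were called in both with the same direction, 56 higher and 116 lower in single-positive cells, where independent lists would share 1.34 and 3.65. Across probe sets, which are not independent replicates, the fold changes had a Pearson r of 0.535 and a Spearman rho of 0.416. Nr4a3, Egr3, Icos, Ikzf4 and Gpr83 were higher and Cd8a, Spc24, Ccnf and Cdc25c lower in single-positive cells of both, although the call of Egr3 in TCR mice was lost with the 30-day gap (adjusted p = 0.0920). Transcription factors of receptor signalling as a list passed only in TCR:HEL mice, while in TCR mice their median shift was -0.05 and their mean shift 0.31 (adjusted p = 0.681), with Nr4a3 and Egr3 rising and Tox2 falling. The probe set called in opposite directions was that of Osbp2, with signals of 92.8 and 25.4 in TCR and 29.7 and 193 in TCR:HEL double-positive and single-positive cells. For the TCR:HEL effect, the fold changes in single-positive and double-positive cells had a Pearson r of 0.0392 and a Spearman rho of 0.0303 across probe sets, and 23 of the 30 probe sets called in single-positive cells had the same sign in double-positive cells.

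**Figure D3:**
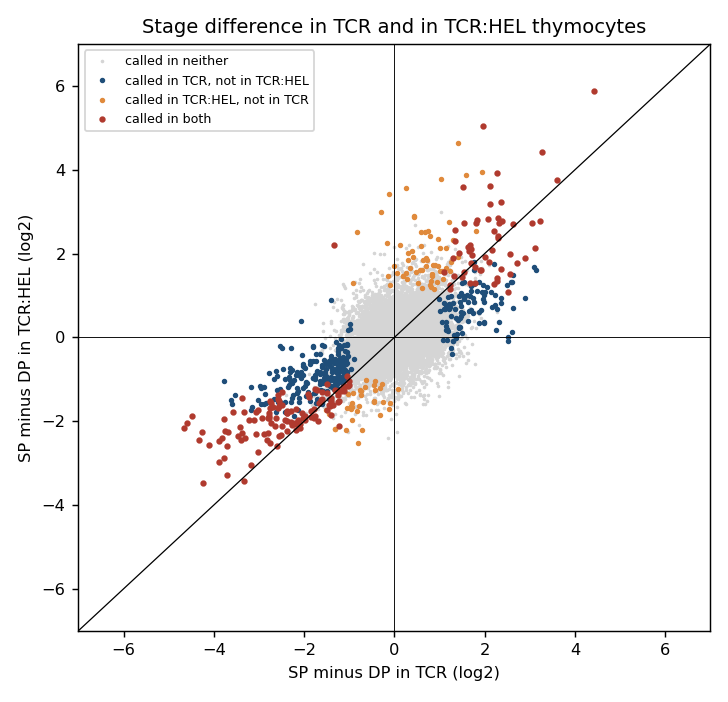
Log2 fold change of single-positive over double-positive cells in TCR (x axis) and TCR:HEL mice (y axis), 1 point per probe set, coloured by where it was called; the diagonal marks equal change. Of the points called in both, 172 share their direction and 1 does not.

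The interaction asked whether the effect of TCR:HEL differed between the stages. Osbp2, which encodes an oxysterol-binding protein, was the gene for which it did, with a TCR:HEL effect of 2.34 in single-positive and -1.19 in double-positive cells, a difference of 3.53 ± 0.50 (SE, adjusted p = 0.0487). Niban1 (2.45 ± 0.40) and Ikzf2 (2.21 ± 0.36) followed with an adjusted p of 0.0715, and Dusp4 had 2.28 ± 0.41 (adjusted p = 0.126). Limma called 1 probe set, with 609 at an unadjusted p under 0.05 where 685 are expected by chance. Osbp2 was called no longer when any array but TCR double-positive replicate 2 was left out, with adjusted p of up to 0.295 without TCR:HEL single-positive replicate 1, and it held in 6 of 25 alternatives.

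Among lists, the TCR:HEL effect on transcription factors of receptor signalling was higher in single-positive than in double-positive cells by a shift of 0.45 (15 genes, adjusted p = 0.000624), and that on cell cycle genes by 0.38 (75 genes, adjusted p = 3.6e-08). Both had an adjusted p of 0.0431 with an estimated correlation, and with the 30-day gap as a block the shifts were 0.33 and 0.35. That of the transcription factors was 0.69 without double-positive replicate 2 of either TCR or TCR:HEL mice and 0.72 without TCR:HEL single-positive replicate 3. The 35-day periods are no test here, since their imbalance is the same at both stages and cancels. Cdca8 (2.15 ± 0.53), Cenpe (2.24 ± 0.57) and Sgo1 (1.93 ± 0.49) had the smallest p-values of the cell cycle list, and Ikzf2 and Fosl2 (2.28 ± 0.70) those of the transcription factors, with 0 members called. Calls of 3 other lists did not hold: costimulatory and inhibitory receptors (0.57, adjusted p = 0.00649, and adjusted p = 0.0749 with an estimated correlation), mature single-positive and egress genes (-0.22, adjusted p = 0.00344, and adjusted p = 0.0759) and oxidative phosphorylation genes (0.41, adjusted p = 0.0270, and adjusted p = 0.203).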

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

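The results here are those for which the effect of TCR:HEL differed between single-positive and double-positive cells by a test of the difference. The tests of explanations below were written before their results were seen, except that of hybridization day for Ikzf2 and Dusp4, chosen after the pairs' values were seen because the first form used genes chosen on the same arrays. The hybridization periods were parted after the hybridization days were seen. Osbp2 had a difference of 3.53 between its TCR:HEL effects at the 2 stages. The lists were transcription factors induced by receptor signals (0.45), cell cycle genes (0.38), costimulatory and inhibitory receptors (0.57), mature single-positive and egress genes (-0.22) and oxidative phosphorylation genes (0.41). The calls of the last 3 were lost with an estimated correlation (adjusted p = 0.0749, 0.0759 and 0.203), and that of the mature genes also without TCR:HEL double-positive replicate 1 (adjusted p = 0.0705). The shift of the mature genes was -0.06 without TCR single-positive replicate 3, -0.37 without TCR single-positive or TCR double-positive replicate 1 and -0.42 without TCR:HEL double-positive replicate 2. The oxidative phosphorylation call was further lost without TCR single-positive replicate 1 (shift 0.22, adjusted p = 0.0968), TCR double-positive replicate 2 (0.17, adjusted p = 0.162), TCR:HEL single-positive replicate 2 (0.32, adjusted p = 0.120) or TCR:HEL double-positive replicate 2 (0.38, adjusted p = 0.108), and the shift was 0.27 without TCR:HEL single-positive replicate 1. Without the arrays of period 1 the receptors and oxidative phosphorylation genes both had an adjusted p of 0.0771. Groups of 3 arrays were not tested for outlying samples.

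Cell cycle genes were higher in TCR:HEL than in TCR single-positive cells. Against hybridization day as the cause, the list was shifted in both pairs of arrays hybridized on the same day, by 0.43 and 0.63. These shifts were above 99.99% and 100% of 10000 random lists of the same size, drawn freely as had been written. Random lists lack the correlation of cell cycle genes with each other, and each pair is 1 array against 1. The percentiles therefore do not measure the spread between mice. For RNA quality, the shift with the Gapdh 5' to 3' ratio as a covariate was 0.64, as without it. The Gapdh ratios were 0.0379, 0.310 and 0.281 in TCR and 0.0856, 0.443 and 0.212 in TCR:HEL single-positive cells. They overlapped, so the covariate could hardly change the shift. The actin ratio, 0.120 and 0.376 on the same-day arrays of period 1, was not tried. RNA quality is thus not excluded. Double-positive cells in the TCR:HEL single-positive gate stay open: their median share would be 17.8% from 54 cell cycle genes and 8.35% from 6 double-positive stage genes, a difference of 9.43 percentage points with a bootstrap 95% interval of -28.7 to 22.7. More dividing cells among those that meet the antigen, the difference the design names, may also account for the shift and were not tested apart from this, and neither were cells of the CD8 lineage.

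Of 41 measured genes on 3 lists of receptor signalling, Ikzf2 and Dusp4 were called higher in TCR:HEL single-positive cells, each gene being counted by its probe set with the highest mean. Another probe set of Nr4a2, also on these lists, was called higher as well. The lists of feedback regulators and of costimulatory and inhibitory receptors had shifts of 0.01 and 0.02 (camera adjusted p = 0.946 and 0.664). Against hybridization day, Ikzf2 and Dusp4 were both called when either same-day pair was left out. In the pair left out they differed by at least 2.25, above 99.6% or more of all genes. With the Gapdh covariate their median log2 fold change was 2.61, as without it. That fit used the arrays on which these genes were chosen, and the Gapdh ratio overlapped between the groups. It therefore cannot decide on RNA quality. Regulatory T cells in the gate are a candidate explanation. The 13 regulatory T cell genes outside the receptor signalling lists passed the bound written beforehand, camera upward at an unadjusted 0.05, with a median shift of 0.16. Only Niban1 (2.51) and Arhgap20 (2.16) of them were called, and the list was not tested without these. Itgae (1.15), Nt5e (0.76), Swap70 (0.56), Plagl1 (0.41), Nrp1 (0.16) and Ikzf4 (0.12) were above 0 without passing. Gpr83 (-0.55), Sdf4 (-0.59), Itih5, Ttc39c and Capg were below 0. The bootstrap 95% interval of the median shift of the 13 genes was -0.22 to 0.76. The whole regulatory T cell list had an adjusted p of 0.119 with an estimated correlation, and its shift within period 1 was -0.07. Foxp3 was not measured, and a response to the antigen in the other cells was not told apart from this and stays open.

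The number of calls was compared with other splits of the same arrays. For the single-positive groups 1 of 10 splits, the real one, reached 30, and the highest other, which put the arrays of period 1 on one side with TCR replicate 2, gave 3. The other 3 splits that part every pair of replicate numbers gave 0. Single-positive against double-positive cells gave 484 in TCR and 271 in TCR:HEL mice, each reached by 1 of 10 splits, with 1 as the highest other. For the double-positive groups all 10 splits gave 0. With 10 splits the share cannot go below 1 in 10, so the splits cannot exclude chance for any of these counts. Splits that mix the groups also put the real difference into the spread within groups, which lowers their counts. For the interaction 18 of 100 relabellings of the mice within each stage gave at least the 1 call found, the highest giving 13, so that chance is not excluded for Osbp2.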

How the results depend on the processing

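Hybridization day as a random block, the 30-day gap, the Gapdh covariate and the fit without the arrays of period 1 were chosen after seeing the data; the other alternatives were fixed before, except for the 35-day gap of the period block, which was set after the hybridization days were seen. No called gene among those named by rule changed sign under any of them, and the signs of the other called probe sets were not followed. Of the called lists, the median shift of regulatory T cell genes between the single-positive groups turned to -0.04 without TCR replicate 2, while the direction of camera's test stayed up. That shift reached 0.37, and its adjusted p ran from 0.00045 to 0.119. Of 108 calls of named genes 64, and of 27 calls of lists 18, passed under every alternative that held them. For lists the random day block was not among the alternatives applied. The filter on 6 arrays removed Trpm1, Osbp2, Fosl2 and Amigo2 and left too few genes on the lists of cytokines, B cells and NK, NKT and gamma-delta cells. Where no cause is named, the cause was not tested.

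Of the counts of called probe sets, that between single-positive groups was 47 with the replicate block, 46 with the random day block (within-day correlation 0.0963), 16 without the arrays of period 1, and 13 to 22 with 1 array left out. For single-positive against double-positive TCR cells it was 303 with only the arrays compared in the fit, 313 with the period block, 240 with the 30-day gap and 293 to 417 with 1 array left out. For TCR:HEL cells it was 334 with only the arrays compared, 432 with array weights and 118 to 219 with 1 array left out. For double-positive groups it was 0 throughout. The interaction count was 0 with a pseudocount of 1, no filter, the filter on 6 arrays, quantile normalization, median centring, the replicate block, the period block and without the arrays of period 1, 4 with a pseudocount of 64, and 0 to 1 with 1 array left out. With the 30-day gap it was 1, a probe set other than that of Osbp2.

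Of the numbers of lists called, that for the double-positive groups was 1 with no filter and with the filter on 6 arrays, 0 with the 30-day gap, an estimated correlation and fry, and 1 to 2 with 1 array left out. For the interaction it was 2 with an estimated correlation, 3 with fry and 4 to 6 with 1 array left out. It was 3 to 5, 6 to 8 and 9 to 10 with 1 array left out for the single-positive groups and for the stages in TCR and TCR:HEL mice. Calls kept while a list's shift moved by more than 1.5 times: with no filter, 0.40 for the cell cycle between single-positive groups, 0.35 for costimulatory and inhibitory receptors between stages in TCR mice, and -0.20 for double-positive stage and 0.29 for regulatory T cell genes between stages in TCR:HEL mice. With a pseudocount of 64 these were 0.42 for the cell cycle, 0.22 for B cells between double-positive groups and 0.19 for transcription factors of receptor signalling between stages in TCR:HEL mice. Mature single-positive genes had 0.42 with the Gapdh covariate and 0.38 with quantile normalization in TCR:HEL mice, and double-positive stage genes -0.47 with the mean of all probe sets of a gene in TCR mice. For lists, moderation without a trend meant camera without a variance trend, and alternatives of array weights and of the arrays in the fit were not run. The random day block did not enter the list tests, so list results there equal those without a block. The pseudocount of 16 compresses fold changes of signals near it, such as those of Osbp2 at 25.4 and Fosl2 at 24.9: Osbp2's difference between stages was 4.44 with a pseudocount of 1.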

Other observations

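These values were picked after the results were seen and were not tested further. In double-positive cells 2 genes that did not pass had higher signals in TCR:HEL. Fcmr had 127 ± 20.9 in TCR and 328 ± 59.1 in TCR:HEL cells, and H2-DMb2 had 52.1 ± 33.7 and 225 ± 131 (SD, n = 3). A second probe set of H2-DMb2 had a log2 fold change of 0.17. Fcmr was also at 70.6 ± 32.9 in TCR and 179 ± 68.6 in TCR:HEL single-positive cells (log2 fold change 1.19 ± 0.35, adjusted p = 0.320). The B cell factors Pax5 (175 and 194) and Ebf1 (55.6 and 55.1) had these mean signals in double-positive TCR and TCR:HEL cells, where the class II gene H2-Aa had 615 and 631.

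Among genes outside the called lists, Trav6-3, a segment of the receptor alpha chain, was lower in TCR:HEL mice at both stages without passing: 333 and 89.1 in double-positive cells and 132 and 61.0 in single-positive cells. Epcam, an epithelial adhesion gene, had 2749 ± 831 in TCR and 1213 ± 294 in TCR:HEL single-positive cells, against 1356 ± 772 and 1718 ± 1030 in double-positive cells (SD, n = 3), with a log2 fold change of -1.15 ± 0.47 between the single-positive groups that did not pass. Dcn, of the same list of thymic epithelium and stroma, had mean signals of 117 and 76.7 in single-positive and 38.1 and 83.4 in double-positive cells, an interaction of -1.39 ± 0.44 that did not pass. The list's other genes, Ccl25 and Sparc, had interactions of -0.15 and 0.04.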
